A study of Mus musculus with 2 samples.

How the data were processed

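Total RNA of newborn mouse skeletal muscle was sequenced from 2 pups, and for each pup a gene table and a transcript table were used. Per the labels' protocols, RNA was extracted with a mirVana kit, 10 ng entered each library, a manual of a SMARTer ultra low input kit is among the protocols, and spike-in RNAs were added. Per the files that accompany the tables, quantification used mm10 and the GENCODE M4 annotation from alignments to the transcriptome. The aligner, the quantifier and their versions are not given in the sources used here, although the column names are those that RSEM writes. The authors deposited expected counts, which are estimated reads per gene or transcript after reads shared between features are split by a model, and a posterior mean of the same estimate. They also deposited TPM, per the file headers, which divides the counts by an effective length and scales each file to a fixed sum, and a TPM from posterior means. The share of a gene's TPM in each transcript was deposited as a percent, per the file headers. The lower and upper bounds of the interval of TPM that the authors deposited, treated as a score here, were not used. Effective length is close to 100 nt under the length, so 2218 short genes with an effective length of 0 can hold no counts, which includes mitochondrial transfer RNAs.

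Each gene table has 43346 gene IDs, 96 ERCC spike-ins, a phiX174 row with 0 counts, and 26248 rows with a number in place of an ID. Names, biotypes and positions came from GENCODE M21, a later annotation of the same build, matched by ID without version, and 42462 gene IDs matched. The others held 0.146% and 0.133% of the counts of replicates 1 and 2. Of 765 genes in the lists, 5 symbols had no match. The numbered rows and the spike-ins stayed out of the gene ratios.

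From these values were computed levels (TPM, mean and SD, n = 2), log2 ratios of pairs of gene forms with 0.1 TPM added to each gene, shares of counts by class, transcript shares, and ratios between the pups. For the last, expected counts were rounded to whole numbers, scaled with TMM in edgeR 4.0.16 (R 4.3.3), and turned to log2 CPM with a prior count of 2, and the ratio of replicate 2 over replicate 1 was taken. DESeq2 1.42.0 gave size factors as an alternative. A list's median ratio was set among 10000 random lists of the same size, drawn with replacement and a fixed seed within 20 bins of mean log2 CPM, among 17004 genes with at least 10 mean counts. Lists whose median lay in the lowest or highest 2.5% of these are said to be higher in replicate 1 or 2. The 2-fold rule asked for 100 mean counts. No test was run, since each pup gave 1 library, and edgeR's quasi-likelihood test has no residual degrees of freedom here. Counting intervals at 95% are exact Clopper-Pearson intervals conditional on the summed counts. A count of 0 was taken as up to 3 counts per library (0.00000742% and 0.00000808% of the counts of replicates 1 and 2). PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

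The 39 gene lists, the 36 pairs, the 20 genes for transcript forms, the limits above and the rule for named genes were fixed before the data were examined. Named are the 10 most abundant nuclear protein-coding and 3 mitochondrial genes, up to 4 leading members of each list, genes of the pairs and of the transcript forms, the 10 protein-coding genes with the largest ratios each way past the 2-fold rule and the largest ratios in lists outside the random lists, and the Y-linked genes and Xist. Hoxa11, Hoxa13, Hoxd13, Pitx1, Tbx4, Tbx5, Snhg11, Nppa, Ucp1, Myod1 and genes of the Xlr family other than Xlr3b were named after their values were seen. On simulated libraries with the real means (negative binomial, 12358 genes), the 2-fold rule found 100% of 100 genes changed 4-fold and 2.06% of 97 genes changed 1.5-fold, and 0 of 12161 unchanged genes passed. The list percentiles put 9 of 200 unchanged simulated lists outside the limits, among 16909 genes. The simulated genes were independent, with a dispersion set by hand, so the rates among unchanged genes and lists follow from these choices. They do not measure false calls in the real libraries. Real genes of 100 to 1000 mean counts had a log2 ratio SD of 0.69 between the pups (scaled median absolute deviation 0.27). Alternatives covered scaling, count filters, pseudocounts, posterior means, fold limits, matching on effective length and leaving out each replicate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.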

Results

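RNA was measured in skeletal muscle of newborn mice of the B6NCrl strain, taken on postnatal day 0. The series holds 1 group with 2 biological replicates, which the labels name as pup 1 (replicate 1) and pup 2 (replicate 2) of 1 pregnancy. The labels give both samples the same donor entry, and they were treated as 2 pups on the wording of the descriptions alone. The labels do not say which muscle was taken, and the sex was not recorded. Each library was made from 10 ng of RNA longer than 200 nt and sequenced as total RNA. The gene tables summed to 40455042 expected counts for replicate 1 and 37151129 for replicate 2. A mean level of at least 1 TPM, the length-corrected unit of the files, was reached by 12495 protein-coding genes. Across the 43346 gene rows, log2(TPM + 1) gave a Pearson's r of 0.990 and a Spearman's rho of 0.945 between the pups, where genes are not independent replicates. A chi-square over 17004 genes came to 63 per degree of freedom, so the files are 2 separate libraries and not a single library deposited again. With 1 group there was no comparison between conditions. Values below are means ± SD with n = 2, the spread is that between the 2 samples and is biological only if these are separate animals, and gene positions are from the GENCODE M21 annotation of mm10.

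The newborn muscle was dominated by transcripts of the fast contractile apparatus. Skeletal actin, Acta1 (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), was the most abundant nuclear protein-coding gene at 53613 ± 5585 TPM. It was followed by the alkali myosin light chain gene Myl1 (ENSMUSG00000061816, chromosome 1, 66924295 to 66945404) at 23446 ± 1544 TPM and by fast troponin C, Tnnc2 (ENSMUSG00000017300, chromosome 2, 164777161 to 164779967), at 19258 ± 255 TPM. The regulatory light chain Mylpf stood at 13057 ± 289 TPM, muscle creatine kinase Ckm at 12078 ± 563, fast troponin T Tnnt3 at 10589.6 ± 22.7 and fast troponin I Tnni2 at 10005 ± 147. The tropomyosins Tpm1 and Tpm2 reached 10483 ± 360.2 and 8373 ± 554 TPM, and the glycolytic enzyme Aldoa 7074 ± 395 TPM. These 10 genes took 13.0% ± 0.928 of all expected counts, and 16.8% ± 0.784 of TPM. All 30 genes of the fast or pan-muscle sarcomere list were at or above 1 TPM, and their median lay at the 98.3 percentile of the expressed protein-coding genes. The mitochondrial genome took 2.96% and 4.58% of the counts of replicates 1 and 2. In deposited TPM it was led by mt-Atp6 at 13903 ± 3049 TPM, mt-Atp8 at 11882 ± 1302 TPM and mt-Nd1 at 5161 ± 1009.8 TPM. Copies of mitochondrial genes on chromosome 1 share reads with them and took a further 0.796% and 1.32%. With the copies' reads added, mt-Co3 had 245236 and 376960 counts and mt-Atp6 222024 and 279904, so this order is uncertain. Protein-coding genes held 94.4% ± 0.954 of the counts and long intergenic RNAs 1.63% ± 0.13.

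Developmental myosins far exceeded the adult forms, while most other sarcomere genes were already in their fast forms. Perinatal myosin heavy chain, Myh8 (ENSMUSG00000055775, chromosome 11, 67277124 to 67308634), stood at 4506 ± 845 TPM and embryonic Myh3 (ENSMUSG00000020908, chromosome 11, 67078300 to 67102291) at 528 ± 53.8 TPM. The adult fast forms of the same gene cluster were at 21.7 ± 2.5 (Myh1, IIx), 15.4 ± 2.65 (Myh4, IIb) and 7.63 ± 0.283 TPM (Myh2, IIa), and the slow form Myh7 on chromosome 14 at 114 ± 4 TPM. The log2 ratio of Myh8 to Myh4 was 8.18 ± 0.02, that of Myh3 to Myh4 5.10 ± 0.10 and that of Myh8 to Myh3 3.08 ± 0.13. Myh8 exceeded Myh1 by 7.68 ± 0.11 and Myh3 exceeded Myh1 by 4.60 ± 0.02 on the same scale, and Myh7 exceeded Myh4 by 2.90 ± 0.30. Cardiac actin, Actc1, which fetal skeletal muscle also uses, was at 6865 ± 123 TPM, a log2 ratio to Acta1 of -2.96 ± 0.12. The slow or cardiac forms of troponin were rarer than the fast ones, with log2 ratios of -3.66 ± 0.33 for Tnnt1 to Tnnt3, -5.10 ± 0.15 for Tnnt2 to Tnnt3, -3.74 ± 0.14 for Tnni1 to Tnni2 and -5.01 ± 0.23 for Tnnc1 to Tnnc2. The light chains followed, at -4.97 ± 0.29 for embryonic Myl4 to Myl1 and -5.41 ± 0.10 for slow Myl2 to Mylpf. Tpm3, the slow tropomyosin gene, stood -4.23 ± 0.18 against Tpm1. An exception was myosin binding protein C, where the slow form Mybpc1 exceeded the fast form Mybpc2 by 3.19 ± 0.16. Of the 36 pairs of gene forms fixed beforehand, the first gene was higher in 10 and the second in 23, in both pups and by more than 3 times the SD, and 3 pairs lay within that limit. The SD measures how closely the 2 samples repeat, and does not cover errors of comparing different genes that both libraries share. With 2 samples an exact sign-flip permutation test cannot pass the usual threshold, so no p-value is given.

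**Figure D1:**
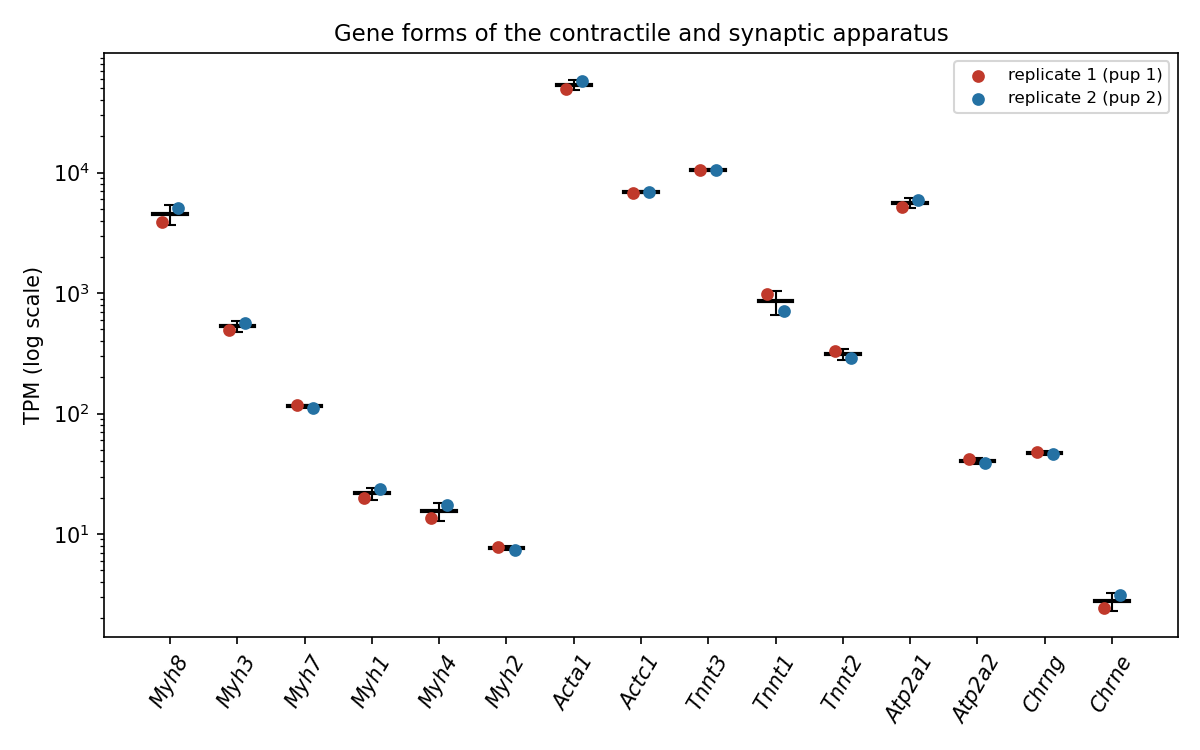
Levels of gene forms of the contractile and synaptic apparatus in newborn muscle, in TPM on a log axis. Red points are replicate 1, blue points replicate 2, thick bars the mean and whiskers 1 SD (n = 2). Myh8 and Myh3 stood above the adult fast myosins Myh1, Myh4 and Myh2, and Chrng above Chrne.

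Calcium handling and the synapse showed the same mix of mature and fetal forms. The fast calcium pump Atp2a1 was at 5571 ± 531 TPM against 40.7 ± 2.27 TPM for Atp2a2, the slow and cardiac pump, a log2 ratio of -7.09 ± 0.22 for Atp2a2 to Atp2a1. A short partial model, Atp2a1-202, held 52.9% of the Atp2a1 TPM but 15.9% and 16.5% of its counts in replicates 1 and 2. The gap was smaller in counts not corrected for length, as given below. Sarcolipin, Sln, a small inhibitor of the pump, reached 5479 ± 1625 TPM. The calsequestrins were closer, at -0.87 ± 0.01 for Casq2 to Casq1, and the ryanodine receptors at -1.52 ± 0.16 for Ryr3 to Ryr1. The fetal gamma subunit of the acetylcholine receptor, Chrng (ENSMUSG00000026253, chromosome 1, 87204657 to 87212694), was at 47 ± 1.63 TPM and the adult epsilon subunit Chrne at 2.77 ± 0.46 TPM, a log2 ratio of 4.05 ± 0.28. All 22 excitation-contraction genes and 17 of 18 neuromuscular junction genes were at or above 1 TPM. So were all 20 genes of the dystrophin complex, led by Cav3 at 249 ± 7.25 TPM. In summed gene TPM dystrophin was above utrophin (log2 ratio -1.39 ± 0.34 for Utrn to Dmd). In TPM, 31.7% of Dmd was in the 79-exon Dmd-203. Retained-intron models held 29.7% (Dmd-212), 13.7% (Dmd-213) and 10.8% (Dmd-205) of the TPM, so the ratio does not compare full-length transcripts. These models are shorter, and by expected counts Dmd-203 held most of Dmd, 74.1% and 71.1% in replicates 1 and 2. On that scale Dmd-212 held 13.0% and 14.1%. Myogenic regulators were led by the late factors Myog at 298 ± 1.12 TPM and Myf6 at 233 ± 16.4 TPM (log2 ratio -0.35 ± 0.10 for Myf6 to Myog), and Myod1 was at 56.6 ± 0.863 TPM. Pax7, the marker of satellite cells, was at 1.75 ± 0.0849 TPM and Pax3 at 0.1 ± 0.0141, a log2 ratio of -3.21 ± 0.17.

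Enzymes of energy metabolism were mostly in their muscle forms. The log2 ratio was -7.76 ± 0.41 for Ckb to Ckm, -5.08 ± 0.43 for Pgam1 to Pgam2, -3.86 ± 0.10 for Ldhb to Ldha, -1.86 ± 0.14 for Eno1 to Eno3 and -4.34 ± 0.50 for the glucose transporters Slc2a1 to Slc2a4. The cytochrome oxidase subunits did not go together, since the liver form Cox7a2 exceeded the muscle form Cox7a1 by 1.45 ± 0.29. Cox6a1 to Cox6a2 (-1.29 ± 0.51), Cox8a to Cox8b (0.31 ± 0.16) and Hk1 to Hk2 (-1.19 ± 0.52) did not exceed 3 SD, which does not show equal levels. Each kept its direction in replicates 1 and 2, at -0.93 and -1.65 for Cox6a1 to Cox6a2, 0.42 and 0.20 for Cox8a to Cox8b and -0.82 and -1.55 for Hk1 to Hk2. All 26 glycolysis genes, all 33 nuclear genes of oxidative phosphorylation and all 25 genes of fatty acid use were at or above 1 TPM, with examples in Gapdh at 5833 ± 48 TPM, Atp5b at 4212 ± 104 TPM and Fabp3 at 913 ± 46.9 TPM. Igf2 was at 2578 ± 308 TPM and exceeded Igf1 by 5.25 ± 0.31. All 34 ribosomal protein genes passed 1 TPM, led by Rps19 at 1292 ± 62.4 TPM. The proliferation lists were present at lower levels, with Cdk1 at 77.7 ± 11.2 TPM among the 25 mitotic genes and Slbp at 55 ± 9.52 TPM among the 24 S phase genes, all of them at or above 1 TPM. Histone genes reached 1 TPM in 18 of 21, led by Hist1h2bc at 292 ± 37.3 TPM, and reads of near-identical histone copies cannot be told apart with certainty. Clock genes reached it in 15 of 16, interferon response genes in 18 of 20, glucocorticoid and fasting genes in 22 of 22 and immediate early and stress genes in 24 of 27.

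Genes of other cell types were detected together with those of muscle. Whether these cells belong to the muscle or to attached tissue was not tested. The leukocyte and the fibroblast and matrix lists were higher in replicate 1, with median log2 ratios (replicate 2 over replicate 1) of -0.50 and -0.22. Endothelium (-0.05) and smooth muscle and pericytes (-0.08) lay within random lists, and liver (0.55) was higher in replicate 2. Fibroblast and matrix genes were high, with Col3a1 at 2197 ± 424 TPM and Sparc at 2187 ± 554 TPM, and all 30 members passed 1 TPM. So did all 20 endothelial genes, for example Egfl7 at 92 ± 1.33 TPM, and all 18 genes of smooth muscle and pericytes, of which Des is also a muscle gene and Acta2 was at 278 ± 14.2 TPM. Schwann cell and nerve genes reached 1 TPM in 17 of 25, led by Pmp22 at 214 ± 23.7 TPM. Blood was present through adult globins, with Hba-a2 at 2529 ± 359 TPM and Hbb-bs at 1445 ± 173 TPM, among 9 of 19 erythroid genes at that level. Embryonic globins were near the floor, with 0 counts of Hbb-bh1 in both libraries and 1 and 2 counts of Hbb-y, and their log2 ratios to Hbb-bs of -13.81 ± 0.17 and -12.87 ± 0.54 depend on the pseudocount. Leukocyte genes reached 1 TPM in 22 of 26, led by the mast cell protease genes Cma1 at 441 ± 178 TPM and Cpa3 at 373 ± 158 TPM. Heart and brown fat markers were low. Only 3 of 14 heart genes reached 1 TPM, and of these Tnnt2 at 310.3 ± 32.1 TPM is also made by developing skeletal muscle, while the next, Tnni3, was at 2.81 ± 0.247 TPM. The brown fat gene Ucp1 was at 0.13 and 0 TPM in replicates 1 and 2, with 6 of 10 genes of that list at 1 TPM, led by Cox8b, which muscle also makes. Liver genes reached 1 TPM in 9 of 11, of which transferrin, Trf, was the highest at 591 and 64.2 TPM in replicates 1 and 2.

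Transcript forms mostly agreed between the pups in which form led. Among the 20 genes fixed beforehand, the leading transcript was the same in both pups in 20, and in 14 it held at least 50% of the gene's TPM in both. The lead was narrow in replicate 2 for Dmd (30.18% against 30.06%) and Clcn1 (38.95% against 38.36%), and by posterior means Clcn1-202 led Clcn1 in replicate 2 (36.77% against 32.97%). Myl1-202, which starts at its own inner first exon (the MLC3f form), held 76.6% ± 2.12 of Myl1 and Myl1-201, with the upstream first exon (MLC1f), 21.1% ± 1.97. Pkm-202, the transcript with the upstream exon of the alternative pair (chromosome 9, 59675029 to 59675195, known as the M1 form), held 84.2% ± 2.4 and Pkm-201, with the downstream exon, 15.8% ± 2.4. The model of Pkm-202 differs in total length between the files and the annotation used here. The leading transcript of Tpm1 (ENSMUST00000113685.5) held 96.8% ± 0.0424 and Fhl1-204 90.7% ± 0.509 of Fhl1. The transcript of Capzb with an extra internal exon of 113 nt, Capzb-203, held 77.3% ± 7.33 and the form without it, Capzb-204, 21.7% ± 7. Atp2a1 was split between the 23-exon Atp2a1-201 at 47% ± 0.714 and Atp2a1-202 at 52.9% ± 0.827, a model of only the last part of the gene that lacks the exon skipped in the neonatal form of the pump, 42 nt long (chromosome 7, 126446545 to 126446586). Short partial models also led Ttn (Ttn-215, 58.2% ± 2.25) and Cacna1s (Cacna1s-203, a processed transcript, 46% ± 2.67), and a retained-intron model led Fn1 (Fn1-202, 58.6% ± 2.31). Of the others, Tnnt3-202 held 27.7% ± 1.66, Tpm2-202 49.9% ± 0.382, ENSMUST00000121503.3 of Tpm3 73% ± 2.04, Dmd-203 31.7% ± 2.2, Bin1-202 98.2% ± 0.113, Ldb3-203 64.2% ± 0.127, Mef2a-208 61.4% ± 2.89, Mef2c-202 57.8% ± 3.83, Mef2d-201 35.3% ± 0.304, Clcn1-201 44.2% ± 7.39 and Camk2b-209 60.5% ± 0.898 of their genes. These shares are model estimates in TPM, and by expected counts Atp2a1-202 held only 15.9% and 16.5% of Atp2a1 in replicates 1 and 2, as its model is short. On the same scale Ttn-215 held 18.2% and 15.7%, Cacna1s-203 11.3% and 13.0% and Ldb3-203 36.1% and 36%. The long Dmd-203 held more than in TPM, 74.1% and 71.1%. The leading transcript was the same by both measures in 16 of the 20 genes.

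Y-linked genes were expressed in both libraries. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) was at 46.7 and 45.7 TPM in replicates 1 and 2, Ddx3y at 27.5 and 29.2, Uty at 6.51 and 9.58 and Kdm5d at 5.11 and 5.03 TPM, while Usp9y and Zfy1 had 0 counts in both, which allows up to 3 counts. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), had 3.52 and 3 expected counts. Of the X-linked list, 5 of 7 were at or above 1 TPM, led by Ddx3x at 33.4 ± 2.26 TPM.

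The largest differences between the pups were in markers of skin, fat and cartilage, which were higher in replicate 1. Of the epidermis list, 19 of 19 tested genes were higher in replicate 1 beyond counting error, and the median log2 ratio of replicate 2 over replicate 1 was -5.69. The keratin Krt1 (ENSMUSG00000046834, chromosome 15, 101845426 to 101850794) had 11507 counts in replicate 1 and 17 in replicate 2, 579-fold (95% counting interval 362 to 995) higher in replicate 1. Loricrin, Lor, had 3393 and 2 counts, a ratio of 1452-fold (95% counting interval 402 to 11992), and the basal keratin Krt5 2158 and 2 counts, a ratio of 923-fold (95% counting interval 255 to 7629). Of the adipocyte list, 14 of 18 genes were higher in replicate 1 and 3 in replicate 2 beyond counting error (median log2 ratio -1.88), among them adipsin, Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), at 1499 and 40 TPM, Scd1 at 102 and 2.75, Cidec at 189.7 and 6.74 and Retn at 281 and 12.2 TPM in replicates 1 and 2. All 15 cartilage genes were higher in replicate 1 (median -3.36, or -3.05 with genes at 0 counts placed at their bound of 3), led by Col2a1 (ENSMUSG00000022483, chromosome 15, 97975602 to 98004695) at 24.1 and 0.27 TPM. Snorc had 62 counts in replicate 1 and 0 in replicate 2, at least 17.7-fold higher. The size of these medians depended on the settings. With TPM and a pseudocount of 1 they were -3.55 for epidermis and -1.47 for cartilage, and from 100 counts -2.17 for cartilage. The level of the epidermis and cartilage lists rests on replicate 1, since 15 of 20 epidermis genes and 13 of 15 cartilage genes had a mean of at least 1 TPM, against 5 and 5 in replicate 2 alone, while for adipocytes it was 16 of 20 with both and 16 in replicate 2 alone. Bone genes had a median of -0.79 (-1.54 from 100 counts and -0.41 with TPM), with Acp5 at 19.1 and 1.27 and Ibsp at 5.64 and 0.34 TPM, and tendon genes -0.54, with Tnmd at 114 and 35.1 TPM.

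**Figure D2:**
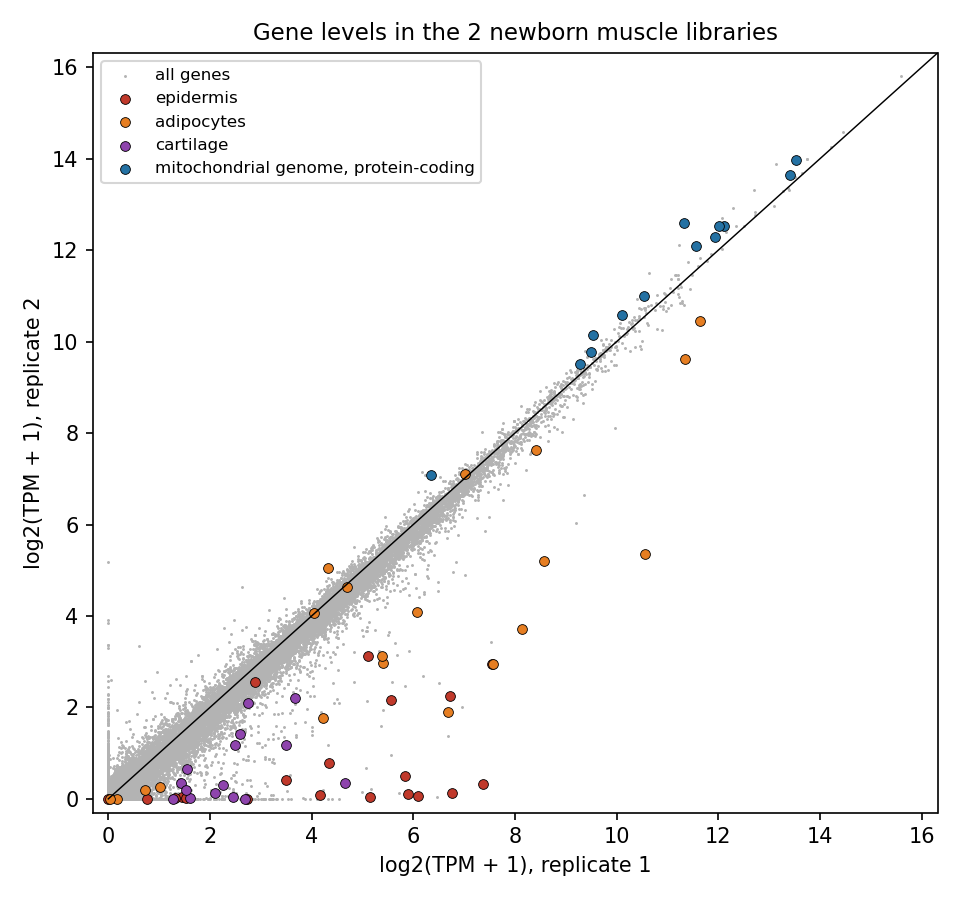
Levels of all genes in replicate 1 (horizontal) and replicate 2 (vertical) as log2(TPM + 1). Grey points are genes, coloured points the members of 4 lists, and the line marks equal levels. Most epidermis, adipocyte and cartilage genes lie under the line and most mitochondrial genes above it.

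Smaller differences in the same direction were seen in 5 other lists. Leukocyte genes were higher in replicate 1 (median log2 ratio -0.50, 21 of 25 beyond counting error), including the mast cell gene Mcpt4 at 151 and 69.2 TPM and Camp at 10.5 and 0.28 TPM. Immediate early and stress genes had a median of -0.43, with Fos at 20.5 and 8.33 TPM, while Hspb1 in the same list went the other way at 1359 and 1942 TPM. S phase genes had a median of -0.24 (20 of 24 beyond counting error, for example Cdc6 at 3.85 and 2.1 TPM) and fibroblast and matrix genes -0.22 (23 of 30, with Col1a1 at 1899 and 1228 TPM). Glucocorticoid and fasting genes had -0.13, with 10 of 22 higher in replicate 1 and 9 higher in replicate 2 beyond counting error, and this list alone fell inside the random lists when TPM was used in place of scaled counts.

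Replicate 2 was higher in transcripts of the mitochondrial genome and of muscle itself. All 13 mitochondrial protein-coding genes were higher in replicate 2 beyond counting error, with a median log2 ratio of 0.60, and mt-Co1 (ENSMUSG00000064351, chromosome M, 5328 to 6872) rose most among them, at 2557 and 6180.1 TPM in replicates 1 and 2. Genes on chromosome 1 that copy part of the mitochondrial genome share reads with it, so the split between them is uncertain. The fast or pan-muscle sarcomere list had a median of 0.31 (27 of 30 beyond counting error, with Ttn at 986 and 1243 TPM), excitation-contraction genes 0.30 (18 of 22, with Sln at 4330.4 and 6628 TPM), the dystrophin complex 0.22 (16 of 20, with Sgca at 118 and 149 TPM) and nuclear oxidative phosphorylation 0.20 (31 of 33, with Cox7a1 at 276 and 383 TPM). Neuromuscular junction genes had 0.18, with Scn4a at 9.3 and 14.5 TPM, glycolysis genes 0.17, with Pygm at 1060.5 and 1269 TPM, and myogenic regulators 0.14, with Myf5 at 38.7 and 49.6 TPM. Imprinted growth genes had 0.27, with Rtl1 at 7.48 and 11.8 TPM, nuclear and small structured RNAs 0.42, with Rian at 665 and 894 TPM, and histones 0.25, with Hist2h4 at 1.88 and 5.43 TPM. Meg3, Rian, Mirg and H19 are in both the imprinted and the nuclear RNA list, so the results of these lists are not independent. Liver genes had 0.55, with Apoa1 at 6.4 and 11 TPM, although Trf in that list was 8.96-fold (95% counting interval 8.64 to 9.3) higher in replicate 1. Of the 39 lists, 10 lay in the lowest 2.5% and 12 in the highest 2.5% of random lists matched on expression, where 1.95 would be expected outside if the members of a list varied independently, which genes of a cell type do not. The medians of the other 17 ran from -0.09 to 0.20, including slow or cardiac sarcomere (0.03) and endothelium (-0.05). Developmental myosins and embryonic muscle (0.15) and fatty acid use (0.15) lay just inside the upper limit, at percentiles 96.37 and 96.25. Both passed it when random lists were also matched on effective length (97.54 and 98.87), but not from 100 counts (95.57 and 93.465). Scaling by spike-ins moved the median of all genes by -0.26 and library totals by -0.10 on the log2 scale, and ratios are given relative to the median gene. Without that correction, spike-in scaling turned the sign of 6 lists (neuromuscular junction, myogenic regulators, dystrophin complex, glycolysis, nuclear oxidative phosphorylation and histones).

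**Figure D3:**
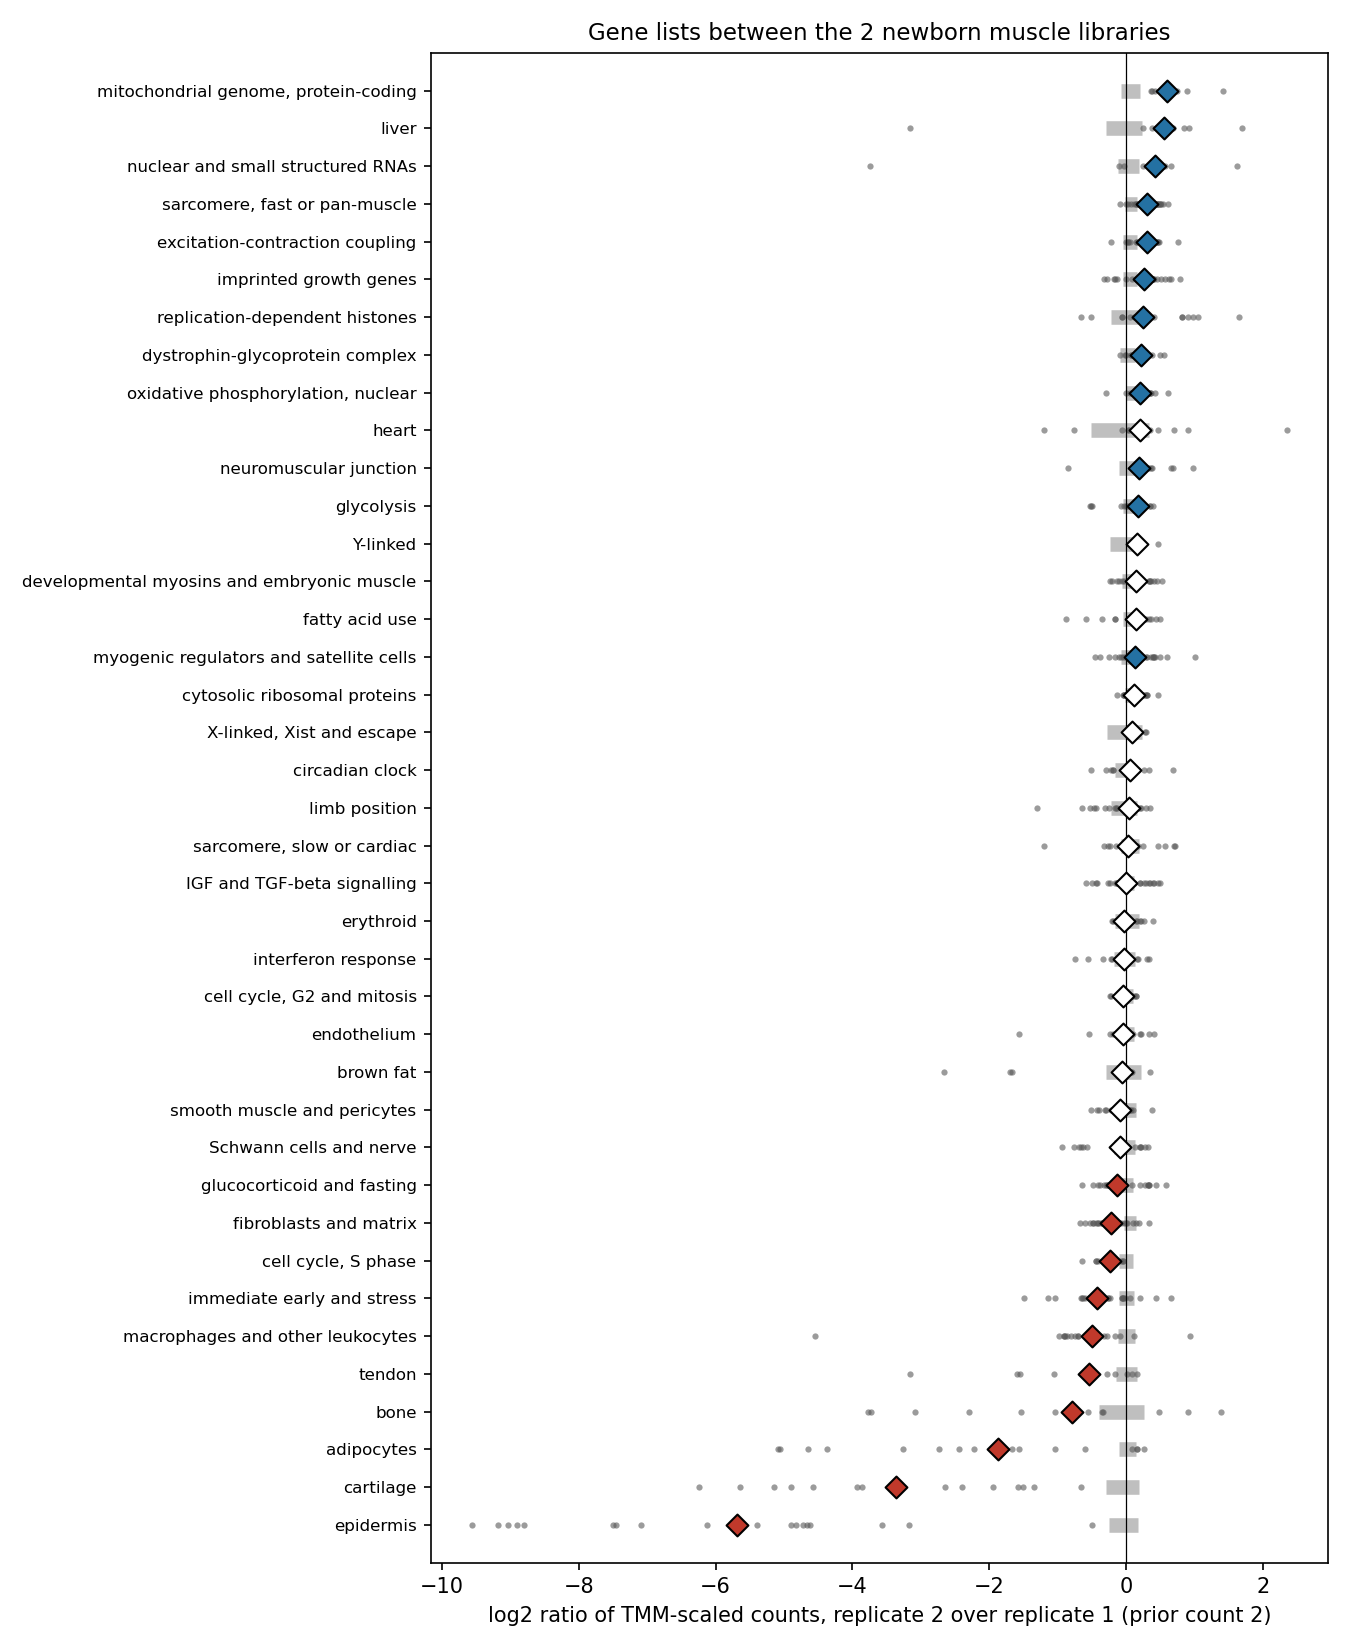
Log2 ratio of replicate 2 over replicate 1 for the 39 gene lists, from TMM-scaled counts. Dots are genes, diamonds list medians (red, higher in replicate 1; blue, higher in replicate 2; white, within random lists) and grey bars hold 95% of the medians of 10000 random lists. Medians ran from -5.69 for epidermis to 0.60 for the mitochondrial genome, and 6 of the blue lists change sign under spike-in scaling before the shift of all genes is taken off.

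Among 12429 genes with at least 100 counts, 277 were at least 2-fold higher in replicate 1 and 20 in replicate 2. All lay beyond counting error, as these limits on counts and fold already imply. The 10 protein-coding genes furthest toward replicate 1 were Lor, Calm4, Krt1, Krt5, Krt14, Hrnr, Lce1m, Casp14, Gm94 and Krt15, of which Hrnr, Casp14 and Gm94 had 0 counts in replicate 2 and were at least 183, 137 and 112-fold higher in replicate 1. Toward replicate 2 the largest was Xlr3b (ENSMUSG00000073125, chromosome X, 73192207 to 73202930), a gene of the X-linked lymphocyte-regulated family, with 25.6 and 449 counts, 20.5-fold (13.6 to 31.2) higher. Among protein-coding genes it was followed by Hist2h4 at 3.19-fold (2.48 to 4.14), Mab21l2 at 3.18-fold (2.35 to 4.31), mt-Co1 at 2.67-fold (2.65 to 2.69), Nell2 at 2.67-fold (1.97 to 3.63) and Gm14296 at 2.64-fold (2.15 to 3.22). Lcn2, Gm14391, Ankrd2 and Notum were the next protein-coding genes, and Ankrd2, a stretch-responsive muscle gene, stood at 70.7 and 142 TPM. Reads shared with similar genes were examined only for the mitochondrial and Xlr genes. The folds of other genes, such as Gm14296 and Gm14391, may therefore depend on how shared reads were split. Leaving out members of the lists outside the random lists, an alternative chosen after seeing the data, left 231 and 17 genes. The counts toward replicates 1 and 2 were 408 and 8 with spike-in scaling and 322 and 12 with library totals. These ratios compare 2 libraries, not conditions, and the intervals cover counting error only. Spike-in RNAs had 406 and 416 counts in all, with 18 and 24 of 96 species detected. The SD of the log2 ratio was 0.43 over the 7 spike-ins with at least 10 counts and 1.14 over 4235 genes of the same count range. Counting alone would give 0.38 for genes with 10 to 100 counts, so most of the spike-in spread can be counting error. The scaled median absolute deviation of those genes was 0.64, so a tail of genes raises their SD. Among genes with 1000 to 10000 counts the SD was 0.46 and the scaled median absolute deviation 0.18, where counting alone would give 0.05.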

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

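The tests of this part were chosen after the result was seen, and when the lists of further markers below were written, the values of 5 of their genes (Krt17, Pkp1, Lypd3, Acsl1 and Chad) had been seen too. Signal appeared in rows that no comparison used. The 26248 rows with a number in place of a gene ID, with a median length of 73 nt, held 36 expected counts in replicate 1 and 29 in replicate 2, above the 3 counts that a count of 0 allows. A row of 255 nt held 27 and 24 of these. 26185 of the rows have an effective length of 0 and can hold no counts.

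Epidermis, fat and cartilage genes were higher in replicate 1. The scaling does not account for it, since common factors moved all genes by -0.26 at most, and TPM with a pseudocount of 1, which is no common factor and brought the cartilage median closest to 0, still left the 3 medians at -1.47 or lower. Nor does a smaller share of muscle RNA alone, which would raise every other cell type alike, because the endothelium list's median exceeded the epidermis list's by 5.64 log2 units. If RNA of skin, fat and cartilage had been mixed into the replicate 1 sample, further markers should be higher there too, and 3 lists of them had medians of -3.57 (epidermis, 19 of 19 higher in replicate 1 beyond counting error), -1.13 (white fat, 16 of 17, with 1 gene shared with a fixed list) and -0.42 (cartilage, 8 of 14). Without the 5 genes seen before, the medians were -3.20, -1.28 and -0.25, at percentiles 0, 0 and 3.7 of random lists. Mixed-in RNA of skin and fat therefore stays a candidate explanation. The further markers are of the same cell types in the same 2 libraries. They cannot tell mixing from other reasons for more RNA of those cells. The further cartilage list could not decide for cartilage, since its median rests partly on genes with many counts in both libraries. Among these were Sox6 (1712 and 1845 counts in replicates 1 and 2) and Frzb (1960 and 1857). Of its 14 tested genes, 8 were higher in replicate 1 and 2 in replicate 2 beyond counting error. The step of mixing is open, and no biological explanation was tested.

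Mitochondrial transcripts were higher in replicate 2. Genes on chromosome 1 (24611535 to 24616197) copy 7 of them, and these copies took 0.796% and 1.32% of the counts of replicates 1 and 2, but the 6 mitochondrial genes without such a copy had a median log2 ratio of 0.48, so the split of reads does not account for the pattern as a whole. Less RNA of other tissues in replicate 2 would raise nuclear muscle genes too. The mitochondrial median, 0.60, exceeded that of nuclear oxidative phosphorylation by 0.40, but the expression of those nuclear genes in other tissues was not measured. The fast or pan-muscle sarcomere list, at 0.31, came closer and still lay below the mitochondrial median. Less RNA of other tissues therefore does not account for the whole, and whether it accounts for a part stays open. With the copies' reads added, mt-Co1 was 2.34-fold higher in replicate 2, while the 12 others had log2 ratios of 0.37 to 0.85. A difference in RNA quality or in the library stays open, and no biological explanation was tested.

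Xlr3b was higher in replicate 2. Reads shared among the near-identical Xlr3, Xlr4 and Xlr5 genes do not account for it, since the summed counts of the 8 members with counts were 44 and 537, a fold of 14.3 (10.5 to 19.9). Of the neighbouring copies, some went the same way and others not, with Xlr3a at 1 and 16.5 counts and Xlr4b at 0 and 28.8 but Xlr4c at 5.17 and 5.12 and Xlr3c at 1.42 and 2.08, though these may be the same reads assigned to several copies. A difference between the pups at this locus stays open and was not tested.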

How the results depend on the processing

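The alternatives were planned before the data were examined, except leaving out list members and adding the reads of nuclear copies to the mitochondrial genes. None of the 22 lists outside the random lists changed direction relative to the random lists. Before the shift of all genes was taken off, 6 of the 22 medians changed sign with spike-in scaling. With TPM, 1 of the 22 did so, that of myogenic regulators (-0.02). Medians of other lists near 0 changed sign too. Of the 22, the glucocorticoid and fasting list alone came inside them, with TPM (median -0.21), and the cause was not tested, while scalings by a common factor could not move a list among random lists. In 8 cases over the other lists a median passed a limit, mostly without a count filter. The numbers of genes at least 2-fold higher in replicates 1 and 2 were 277 and 20 as reported, 829 and 241 from 10 counts, 1551 and 1160 without a filter, 64 and 4 from 1000 counts, 607 and 149 at 1.5-fold and 164 and 4 at 3-fold. They were 408 and 8 with spike-ins, 322 and 12 with library totals and 254 and 9 with TPM. Pearson's r was 0.983 with a pseudocount of 0.1 and 0.973 over genes of at least 1 TPM, where Spearman's rho was 0.969. In TPM, the mitochondrial genome held 6.47%, the 10 highest genes 16.8% and protein-coding genes 87.8%, since TPM divides by length. With a pseudocount of 1, the log2 ratio Myh8/Myh4 was 8.10 and the log2 ratio Chrng/Chrne 3.68. From counts not corrected for length they were 8.21 and 4.78, the log2 ratio Tnnt2/Tnnt3 -4.92 and the log2 ratio Atp2a2/Atp2a1 -5.92. Leaving out either replicate put the log2 ratio Myh8/Myh4 at 8.16 to 8.20. By expected counts in place of TPM, 16 of 20 genes kept their leading transcript. No spike-in reached 100 counts, so that alternative gave no value, and spike-in scaling rests on 406 and 416 counts. No paired analysis was possible because the series holds 1 group.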

Other observations

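The lists of this part were fixed beforehand, and single genes outside the rule for named genes were chosen after their values were seen. Genes of limb position were expressed in both pups. The posterior genes Hoxa10 at 36.2 ± 4.86 TPM, Hoxc10 at 20.8 ± 0.0424 TPM and Hoxa9 at 17.1 ± 0.354 TPM were the highest Hox genes of the list, and Tbx15 was at 32.3 ± 0.672 TPM. The hindlimb factors Pitx1 (ENSMUSG00000021506, chromosome 13, 55825051 to 55836192) and Tbx4 (ENSMUSG00000000094, chromosome 11, 85886422 to 85916097) were at 3.59 ± 0.0141 and 1.94 ± 0.0424 TPM, and the forelimb factor Tbx5 (ENSMUSG00000018263, chromosome 5, 119832668 to 119885219) at 0.16 ± 0.0141 TPM. Hoxa13 (0.04 and 0.02 TPM in replicates 1 and 2) and Hoxd13 (0.03 and 0), genes of the far end of the limb, were near the floor. Of 26 genes in the list, 16 were at or above 1 TPM and the median log2 ratio between the pups was 0.04, within random lists, with 4 members higher in replicate 1 and 4 in replicate 2 beyond counting error. Among these Hoxa11 was at 3.17 and 1.17 TPM in replicates 1 and 2.

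Imprinted genes were among the most abundant in this tissue. Meg3 was at 3436 ± 322 TPM, Igf2 at 2578 ± 308, H19 at 2396 ± 345 and Gnas at 2348 ± 37.9 TPM, and 22 of 23 genes of the list were at or above 1 TPM, with the list's median at the 93.9 percentile of expressed protein-coding genes. Meg3, Rian and Mirg, noncoding RNAs of a single imprinted domain on chromosome 12, together with Rtl1 of the same domain, had log2 ratios of 0.39, 0.57, 0.65 and 0.80 between the pups (replicate 2 over replicate 1). In the list of nuclear and small structured RNAs, Malat1 was at 4975 ± 637 TPM and 11 of 14 reached 1 TPM. Snhg11 went against that list, at 1.53 and 0.08 TPM in replicates 1 and 2.

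Gene ID ENSMUSG00000081977, which the annotation used here does not name, had 2976 counts in replicate 1 and 1 in replicate 2, a ratio of 2546-fold (95% counting interval 457 to 100617). The atrial peptide gene Nppa had 4.27 and 25.1 counts, 6.87-fold (2.52 to 28.9) higher in replicate 2, while the heart list as a whole had a median log2 ratio of 0.20, within random lists.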
